A study of Mus musculus with 4 samples.

How the data were processed

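Chromatin immunoprecipitation with an antibody against acetylated histone H3 was sequenced from left ventricles of male C57BL6 mice aged 10 to 12 weeks. Per the labels, the mice had transverse aortic constriction (TAC), a surgery that narrows the aorta and loads the left ventricle with pressure, or a sham operation. They then received injections 2 times a day for 4 weeks of the solvent DMSO (vehicle, Veh) or of trichostatin A (TSA), an inhibitor of histone deacetylases, at 0.6 mg per kg per day. Each of the 4 groups, Sham Veh, Sham TSA, TAC Veh and TAC TSA, is represented by 1 library. Per the labels' protocols, tissue was fixed for 10 minutes in 1% formaldehyde, libraries were amplified over 15 PCR cycles, and fragments of about 250 bp were sequenced on an Illumina Genome Analyzer. The labels of both sham libraries, and of neither TAC library, cite an earlier deposit, so sham and TAC libraries may not have been made together.

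The authors deposited a table of raw read counts per promoter of each RefSeq transcript, whole numbers that were not normalised, and 6 lists of regions that differ between libraries. The submitters' processing notes name BWA 0.5.9, MACS 1.4.1 and the mm9 build. The role of each tool, the promoter window, the counting tool, the handling of duplicate reads and any subtraction of input are not given in the sources used here. The region lists carry a score per region that the authors deposited, which is the caller's own value and was used only to rank regions within a list. No column of per-sample values was left unused.

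Of 31594 RefSeq IDs, 31115 (98.5%) were matched to a gene symbol of the GRCm38.p6 assembly, which was used for names only. The 479 unmatched IDs held 1.11% of the counts and were left out. Each of the 23631 genes was represented by the ID with the highest mean count, and the 22835 genes with a mean count of at least 10 were kept. The total promoter count was 9612616 in Sham Veh, 9905553 in Sham TSA, 8873302 in TAC Veh and 6842296 in TAC TSA. No pair of libraries held identical values. Neighbouring or overlapping genes share promoter reads (Myh6, its antisense transcript Mhrt and Mir208a, for example), and members of multigene families may share reads, so their values are not independent.

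Libraries were scaled by the trimmed mean of M-values (TMM, edgeR 4.0.16 in R 4.3.3). With 1 library per group no test between conditions was made for the pairwise comparisons. The log2 ratio of scaled counts is given with its exact 95% conditional (Clopper-Pearson) interval. These intervals cover counting error only, compare 2 libraries and not 2 conditions, and treat PCR reads without molecular identifiers as independent. A promoter was counted as apart when the ratio was at least 1.5-fold and its interval excluded 1. The count was set beside the mean of 20 sets of Poisson counts simulated with no difference. For 19 gene lists fixed before the data were examined, the median log2 ratio was placed among the medians of 10000 random lists matched on mean count, each member being replaced by 1 of the 200 genes nearest in count. A list was said to stand apart below percentile 2.5 or above percentile 97.5. These percentiles describe the libraries and treat genes as independent. All 10 cardiomyocyte markers are also members of another list, 7 of them of the adult sarcomere list.

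The only test used all 4 libraries in an additive model of surgery and drug (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, threshold 0.05). Its 1 residual degree of freedom is the surgery by drug interaction, and the fit estimated 1 spread for all genes, so a gene's own interaction does not enter its p-value. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives. Correlations are across genes, which are not independent replicates, on log2(scaled count + 2). Region lists were compared by an overlap of at least 1 bp, beside 50 random placements on the same chromosomes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

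The methods were tested on simulated data. In counts simulated for TAC Veh over Sham Veh, over 22835 genes, the 1.5-fold rule found 50% of 100 promoters changed 1.5-fold and 97% of 100 changed 2-fold, with 201 of 22635 unchanged promoters counted as apart. The 50% follows from a threshold placed at the simulated difference. The additive fit was run on separate simulated counts, with its own estimate of spread and no interaction. It found 59% of 100 promoters with a 1.5-fold surgery effect and 82% of 100 with a 2-fold one, with 1 false call. The drug effect and an interaction were not simulated, so this does not bear on calls where an interaction is present. Of 200 random lists of 20 genes for TAC Veh over Sham Veh, 5% lay outside the central 95% with no shift and 100% with a shift of 0.2. The 5% follows from drawing the lists at random, whereas members of the fixed lists may vary together.

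Genes were named by a rule written before the data were examined. Per comparison it takes 24 anchor genes whatever their value, the 10 highest and 10 lowest protein-coding genes ranked by the interval bound nearest 1, and the 2 highest and 2 lowest members of each list. Symbols of predicted genes, microRNAs and olfactory or vomeronasal receptors were left out of the ranking, and genes called by the additive fit are named beside their test. Alternatives were total-count, DESeq2 and silent-promoter scaling (on olfactory and vomeronasal receptor promoters), loess scaling on mean count, other count filters, each RefSeq ID taken on its own, a 2-fold threshold, thinned counts, other prior counts, other test tools and stricter region lists. Restricting the count to the upper part of mean counts was added after the data were seen. An annotation of the mm9 build was not used here, so regions were not assigned to genes.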

Results

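Acetylation of histone H3 at promoters, a mark of active chromatin, was profiled in the left ventricle in a 2 by 2 design of pressure overload (TAC or sham surgery) and HDAC inhibition (TSA or vehicle). Each of the 4 groups had 1 library, so no value below has a replicate. Total promoter counts ranged from 6842296 (TAC TSA) to 9905553 (Sham TSA), with a median per gene of 231 counts in Sham Veh, 235 in Sham TSA, 213 in TAC Veh and 169 in TAC TSA. Promoters of olfactory and vomeronasal receptors, 1455 genes silent in heart, served as a measure of background. They held 0.420% of counts in Sham Veh (exact binomial 95% interval 0.415 to 0.425), 0.427% in Sham TSA (0.422 to 0.431), 0.505% in TAC Veh (0.50 to 0.511) and 0.677% in TAC TSA (0.670 to 0.685). Log2 ratios follow with 95% intervals for counting error and are relative to the bulk of promoters. Scaling on the receptor promoters instead shifts the median of all genes by −0.24 in TAC Veh over Sham Veh, −0.61 in TAC TSA over Sham TSA and −0.38 in TAC TSA over TAC Veh.

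The first comparison, TAC Veh over Sham Veh, asked how pressure overload altered promoter acetylation. The medians of lists for the contractile and electrical apparatus of the adult heart were lower in the TAC Veh library than those of count-matched lists. The medians of the matrix, fibroblast and leukocyte lists were higher relative to the bulk of promoters, and near 0 with receptor-promoter scaling. Myh6, the adult alpha myosin heavy chain, was 1.79-fold lower (log2 ratio −0.84, −1.05 to −0.64). Thbs4, a matrix glycoprotein, was 2.55-fold higher (1.35, 0.81 to 1.91). Cardiomyocyte markers had a median log2 ratio of −0.60, a difference of −0.59 from count-matched lists, and 6 of 10 were apart and lower.

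Within the muscle lists of TAC Veh over Sham Veh, 4 of 20 adult sarcomere promoters were apart and lower (list median −0.41, percentile 0), among them Myh6 and cardiac actin Actc1 (−0.86, −1.11 to −0.61). Of 25 calcium handling and ion channel promoters 4 were lower (median −0.31). They included the atrial potassium channel Kcnj3 (−1.04, −1.44 to −0.65), the L-type calcium channel Cacna1c (−0.73, −0.97 to −0.49), the ryanodine receptor Ryr2 (−0.71, −0.99 to −0.43) and phospholamban, Pln (−0.59, −0.83 to −0.36; −0.57 with loess scaling, which is short of 1.5-fold). The calcium pump Atp2a2 was at −0.18 (−0.33 to −0.02) and did not reach 1.5-fold. Fatty acid oxidation genes had a median of −0.20, with 3 of 26 lower, including the uncoupling protein Ucp3 (−0.87, −1.13 to −0.61) and the fatty acid transporter Cd36 (−0.66, −0.89 to −0.44). Lists of oxidative phosphorylation (−0.10), protein degradation and atrophy (−0.19), cardiac transcription factors (−0.12) and endothelial markers (−0.17) also lay below their matched lists. Among the transcription factors Tbx5 was at −0.81 (−1.09 to −0.55) and the smooth and cardiac muscle coactivator Myocd at −0.69 (−0.96 to −0.42).

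On the higher side, extracellular matrix and fibrosis genes had a median of 0.25 in TAC Veh over Sham Veh, with 4 of 31 apart and higher, including periostin, Postn (0.79, 0.45 to 1.13). Fibroblast markers were at 0.25 (Mfap5 0.61, 0.30 to 0.91) and leukocyte markers at 0.28 (the integrin Itgam 0.60, 0.15 to 1.05), each with 1 member apart and higher. With loess scaling Itgam was at 0.55 and no longer apart. Cell cycle genes were at 0.06, percentile 99.2, with none of 21 apart. The fetal and hypertrophy list as a whole stayed within its matched lists (median −0.07), with 2 of 26 members higher and 2 lower. Skeletal actin Acta1 (0.77, 0.43 to 1.12) and the natriuretic peptide Nppb (0.63, 0.28 to 0.98) were higher, and Nkx2-5 (−0.64, −0.89 to −0.39) and Csrp3 (−0.63, −0.91 to −0.35) lower. Nppa (0.44, 0.06 to 0.81), the fetal myosin Myh7 (0.33, 0.06 to 0.59) and Col1a1 (0.49, 0.25 to 0.73) had intervals above 0 without reaching 1.5-fold. The glycolysis (−0.05), HDAC and acetyltransferase (−0.03), immediate early (−0.04), autophagy (−0.05), renin-angiotensin and adrenergic (−0.04) and smooth muscle (0.05) lists lay within their matched lists.

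Over all genes, the lowest ratio by the ranking rule in TAC Veh over Sham Veh belonged to the carboxylesterase Ces1d (−1.39, −1.81 to −0.98). The myosin light chain kinase Mylk3 (−0.92), the troponin-interacting kinase Tnni3k (−1.07), alcohol dehydrogenase Adh1 (−1.0), Asb2 (−0.81) and Slc25a34 (−0.79) completed the lowest 10 with genes given above. Besides Thbs4, the highest included the acute-phase gene Serpina3n (1.13, 0.75 to 1.52) and the thyroid hormone deiodinase Dio2 (1.01, 0.65 to 1.38). The others were low-count promoters of genes such as Serpinb3b, which had 3 counts in Sham Veh and 17 in TAC Veh (2.60, 0.81 to 5.01). In total 440 promoters were apart and higher and 133 lower, against 97.2 and 99.7 in simulated counts without a difference. Scaling by loess on mean count changed this split to 199 and 244, since weak promoters had higher ratios in the TAC Veh library. Of the 19 lists, 12 stood apart, where 0.95 would by chance if genes varied independently. With loess scaling 10 did, without cardiac transcription factors (percentile 6.13) and cell cycle genes (percentile 93.5). With receptor-promoter scaling the muscle lists stayed lower, and the medians of matrix (0.00), fibroblast (0.01) and leukocyte genes (0.04) were near 0. Acta1 (0.53), Nppb (0.38) and Postn (0.54) were then below 1.5-fold, and the fetal list had 0 members higher and 4 lower. Thbs4 was then the only matrix gene apart, and no fibroblast or leukocyte gene was higher.

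**Figure D1:**
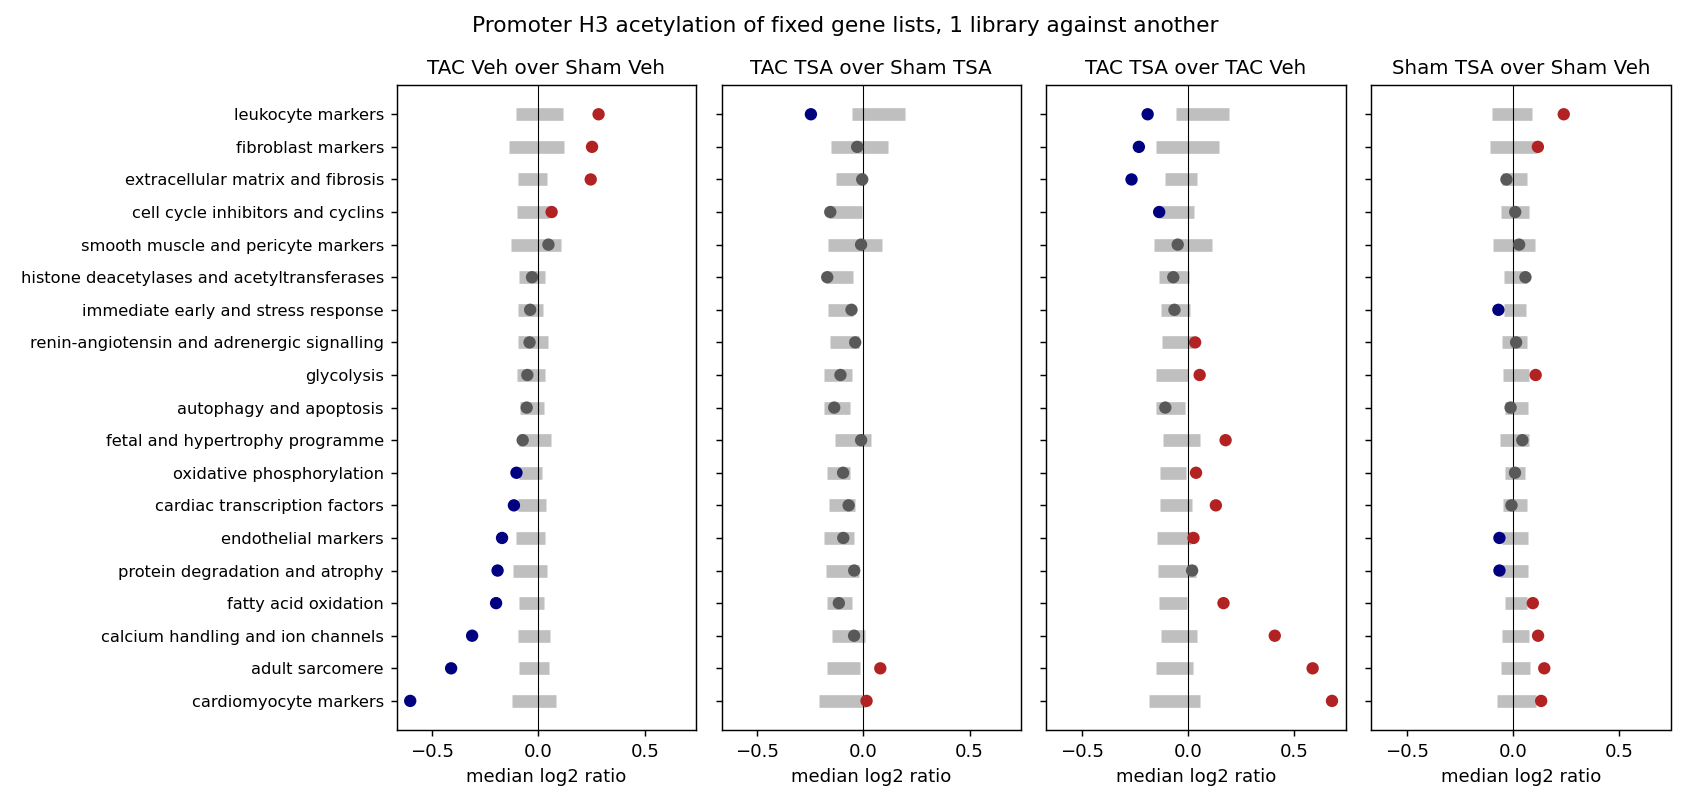
Median log2 ratio of promoter counts (horizontal axis) for the 19 fixed gene lists (vertical axis) in the 4 comparisons of 1 library with another. Grey bars span the central 95% of count-matched random lists, red points lie above and blue points below it. Cardiomyocyte markers lie at −0.60 in TAC Veh over Sham Veh and at 0.68 in TAC TSA over TAC Veh.

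The comparison of TAC TSA with TAC Veh asked what TSA did under pressure overload. The medians of the heart muscle lists were higher in the TAC TSA library than those of count-matched lists, and the medians of the matrix, fibroblast and leukocyte lists were lower. Myh6 was 2.17-fold higher (1.12, 0.91 to 1.33) and Ces1d 2.75-fold higher (1.46, 1.03 to 1.89). Cardiomyocyte markers had a median of 0.68, with 8 of 10 apart and higher, and adult sarcomere genes a median of 0.59, with 10 of 20 higher. Extracellular matrix genes had a median of −0.27, with 4 of 31 apart and lower, among them Postn (−0.85, −1.24 to −0.48) and the protease inhibitor Timp1 (−0.78, −1.29 to −0.28).

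Of the calcium handling and channel genes 7 of 25 were higher in TAC TSA than in TAC Veh (median 0.41). These included Kcnj3 (1.41, 1.02 to 1.82), the ATP-sensitive potassium channel Kcnj11 (0.97, 0.73 to 1.20), Cacna1c (0.86, 0.61 to 1.11), Ryr2 (0.78, 0.48 to 1.07) and Pln (0.61, 0.37 to 0.86). Actc1 was at 1.15 (0.90 to 1.4). Cardiac transcription factors had a median of 0.13 with 4 of 23 higher, among them Tbx5 (0.95, 0.67 to 1.23) and Myocd (0.79, 0.51 to 1.08). The fetal and hypertrophy list was at 0.18 with 4 of 26 higher, including Nkx2-5 (0.78, 0.52 to 1.04) and the pacemaker channel Hcn4 (0.75, 0.42 to 1.09). Fatty acid oxidation genes were at 0.17 with 3 of 26 higher, including Ppara, the lipid-sensing nuclear receptor (0.78, 0.56 to 1.00), and the fatty acid binding protein Fabp3 (0.76, 0.58 to 0.94). Oxidative phosphorylation (0.04; 3 of 27 higher, Cox8b 0.83, 0.57 to 1.09) and glycolysis (0.05; 2 of 18 higher, the muscle enzyme Pgam2 0.88, 0.63 to 1.14) lay above their matched lists, as did endothelial markers (0.02) and the renin-angiotensin and adrenergic list (0.03). Protein degradation genes were at 0.02, percentile 94.4, although 3 of 14 were higher, among them the muscle ubiquitin ligases Trim63 (0.81, 0.50 to 1.13) and Trim55 (0.79, 0.45 to 1.14).

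Fibroblast markers were at −0.23 in TAC TSA over TAC Veh, with none of 12 apart, and leukocyte markers at −0.19, where the pan-leukocyte phosphatase Ptprc (−0.65, −1.17 to −0.15) was the member apart. Cell cycle genes were at −0.14, percentile 2.04. Acta1 was at −0.51 (−0.87 to −0.15) and Col1a1 at −0.27 (−0.52 to −0.02), neither 1.5-fold lower. With loess scaling Acta1 was at −0.60, past 1.5-fold. Of the natriuretic peptides Nppa was at −0.05 (−0.43 to 0.33) and Nppb at 0.37 (0.06 to 0.68). The metabolic regulators Ppargc1a (0.45) and Pdk4 (0.47) and the stress gene Ankrd1 (0.44) did not reach 1.5-fold. The HDAC and acetyltransferase (−0.07), immediate early (−0.06), autophagy (−0.11) and smooth muscle (−0.05) lists lay within their matched lists. The lowest promoter was that of the transcription factor Runx1 (−0.99, −1.22 to −0.76). It was followed by Svep1 (−0.89), the complement component C1qb (−0.87), Postn, Slfn2 (−0.66), the lysosomal protease Ctss (−0.84), Cmklr1 (−0.62), the lysyl oxidase Loxl3 (−0.61), Garem2 (−0.75) and Dok1 (−0.61). With loess scaling Cmklr1, Loxl3 and Dok1 were no longer 1.5-fold lower. Besides genes already given, the highest 10 held Fam174b (1.15), Asb2 (0.95), Pcdhga2 (1.31), Cntn3 (1.92) and Glyatl3 (1.66).

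In this comparison 927 promoters were apart and higher in TAC TSA and 78 lower, against 107 and 113 in simulated counts. With loess scaling the split was 301 and 243. Among promoters in the upper part of mean counts (at least 228 counts), a restriction chosen after the data were seen, 73 were higher and 13 lower. Of the 19 lists 14 stood apart (13 with loess scaling, without the renin-angiotensin and adrenergic list), and all of these values rest on the same TAC Veh library as the first comparison. With receptor-promoter scaling the medians were 0.29 for cardiomyocyte, 0.20 for adult sarcomere and 0.02 for calcium handling genes, while those of the other lists given above as higher turned negative (fatty acid oxidation −0.22, fetal −0.21). Of the members given as higher, 2 cardiomyocyte, 2 sarcomere and 1 calcium handling gene then stayed so, and the fetal list had 0 higher and 4 lower.

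**Figure D2:**
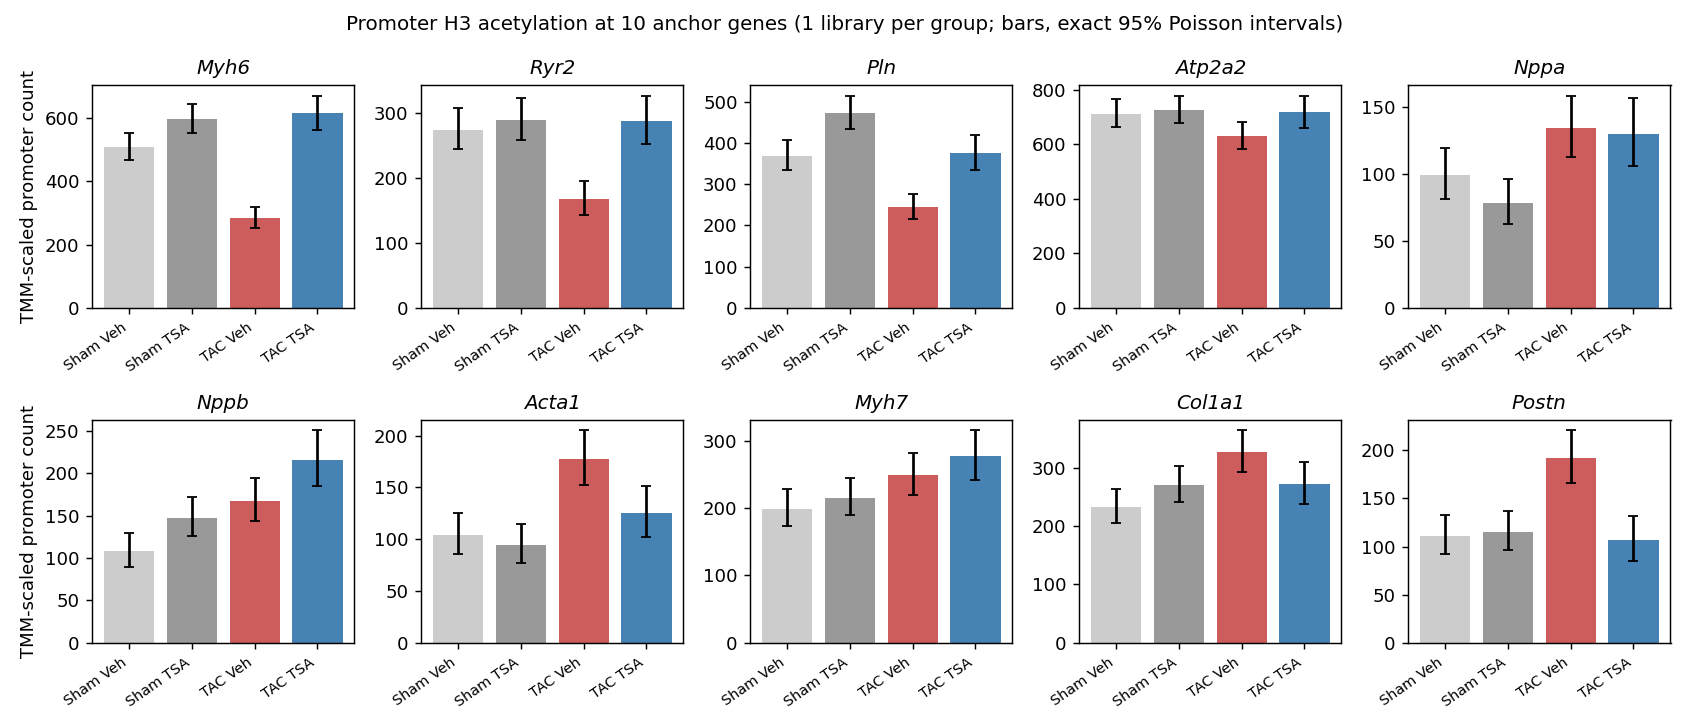
TMM-scaled promoter counts (vertical axes, starting at 0) of 10 anchor genes in each of the 4 libraries, with exact 95% Poisson intervals for counting error. The bar for Myh6 is lowest in TAC Veh, at 1.79-fold below Sham Veh, and that for Postn is highest in TAC Veh.

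TAC TSA over Sham TSA compared pressure overload between treated animals. Here the heart muscle lists were not lower. Adult sarcomere genes had a median of 0.08, above their matched lists (percentile 100), cardiomyocyte markers 0.02 (percentile 97.9) and calcium handling genes −0.04 (percentile 77.8), and Myh6 was at 0.04 (−0.13 to 0.21). Nppa was higher (0.73, 0.31 to 1.16), as were Mef2c (0.78, 0.07 to 1.5) and angiotensinogen, Agt (0.65, 0.32 to 0.98), while Nppb was at 0.55 (0.24 to 0.87). With loess scaling Nppa (0.57) and Mef2c (0.33, on 32 and 40 counts) were below 1.5-fold. Leukocyte markers were lower, with a median of −0.25 and Ptprc at −0.78 (−1.29 to −0.29).

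In TAC TSA over Sham TSA the complement gene C1qb was lowest (−1.04, −1.39 to −0.70), followed by Slfn2 (−0.84), Capza2 (−0.82), the class I histocompatibility gene H2-T24 (−0.78), the lectin Clec2d (−0.62), Apobec1 (−0.69), the microglial and macrophage receptor P2ry12 (−0.89), Rtp4 (−0.62), Dab2 (−0.61) and the interferon-induced GTPase Iigp1 (−0.67). With loess scaling Clec2d, Rtp4 and Dab2 were no longer 1.5-fold lower. The remaining lists lay within their matched lists. Their medians were −0.01 for matrix, −0.03 for fibroblast, −0.09 for endothelial and −0.01 for smooth muscle genes, −0.01 for the fetal list, −0.12 for fatty acid oxidation, −0.10 for oxidative phosphorylation and −0.11 for glycolysis. They were −0.07 for cardiac transcription factors, −0.17 for HDACs and acetyltransferases, −0.06 for immediate early, −0.16 for cell cycle, −0.14 for autophagy, −0.04 for protein degradation and −0.04 for renin-angiotensin and adrenergic genes.

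The highest promoters of TAC TSA over Sham TSA had few counts, such as the keratin-associated Krtap22-2 (32 counts against 8; 2.46, 1.31 to 3.79), Spata31 (2.58), Ugt2b36 (2.20), Tas2r129 (2.21) and Brinp1 (1.78). Receptor promoters as a class had a median of 0.67, with 372 of 1274 apart and higher and none lower. The counts were 1643 higher and 47 lower over all genes, against 112 and 113 in simulated counts. With loess scaling they were 189 and 305, and among promoters of at least 228 mean counts 3 and 11. The median ratio was 0.68 in the lowest decile of mean count and −0.13 in the highest. Of the 19 lists 3 stood apart, and 5 with loess scaling, which added immediate early (percentile 97.8) and cell cycle genes (percentile 2.37). With receptor-promoter scaling the medians of adult sarcomere (−0.52) and cardiomyocyte genes (−0.58) turned negative.

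**Figure D3:**
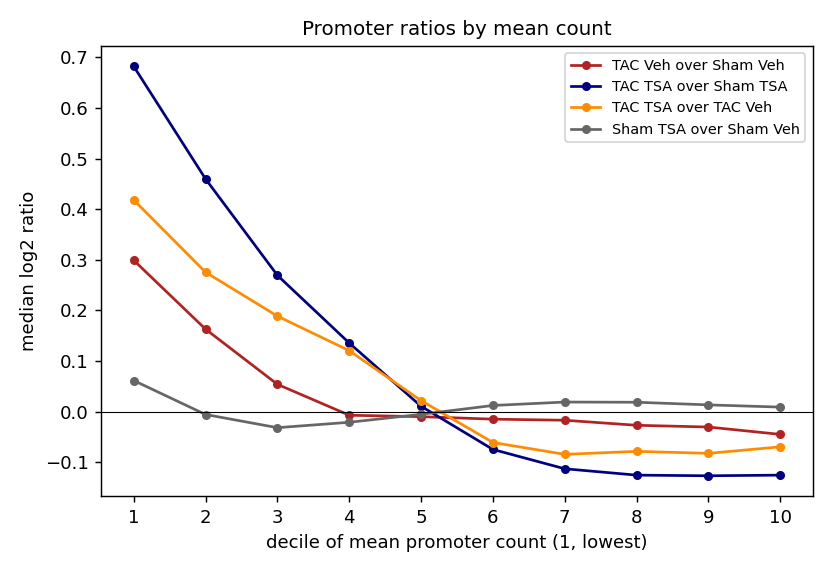
Median log2 ratio (vertical axis) by decile of mean promoter count (horizontal axis) for the 4 comparisons. The lowest decile lies at 0.68 in TAC TSA over Sham TSA, 0.42 in TAC TSA over TAC Veh, 0.30 in TAC Veh over Sham Veh and 0.06 in Sham TSA over Sham Veh.

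Sham TSA over Sham Veh asked what TSA did without pressure overload. The counts were close to those of simulated libraries, with 133 promoters higher and 133 lower against 97.6 and 99.3. Muscle lists were slightly higher with TSA, without any member apart. The medians were 0.15 for adult sarcomere, 0.13 for cardiomyocyte, 0.12 for calcium handling, 0.09 for fatty acid oxidation and 0.11 for glycolysis genes, each above percentile 99. Myh6 was at 0.23 (0.07 to 0.40), Mybpc3 at 0.47 (0.27 to 0.68) and Kcnj3 at 0.54 (0.26 to 0.82). Leukocyte markers had a median of 0.24 (percentile 100), with Ptprc at 0.64 (0.21 to 1.08), and fibroblast markers 0.12 (percentile 98).

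Endothelial (−0.06), immediate early (−0.07) and protein degradation genes (−0.06) were slightly lower in Sham TSA than in Sham Veh, where the heat shock gene Hspa1a (−0.59, −0.88 to −0.30; −0.58 and not apart with loess scaling) was apart. The other lists lay within their matched lists, at −0.03 for matrix, 0.04 for fetal, 0.01 for oxidative phosphorylation, −0.01 for cardiac transcription factor, 0.06 for HDAC and acetyltransferase, 0.01 for cell cycle, −0.01 for autophagy, 0.01 for renin-angiotensin and adrenergic, and 0.03 for smooth muscle genes. Thbs4 (1.02, 0.47 to 1.59) and Serpina3n (0.94, 0.56 to 1.33), both high in TAC Veh over Sham Veh, were also high here, and both comparisons divide by the same Sham Veh library (41 and 86 counts). So were the leukocyte genes Ms4a6c (1.13, 0.66 to 1.62) and Ms4a4c (1.24, 0.39 to 2.15, on 17 and 41 counts) and the chemokine Ccl12 (0.95, 0.50 to 1.4). The rest of the highest 10 were the low-count promoters of Mageb18, Nlrp9b, Catsperb, Tas2r122 and Vwc2l. Mageb18 ranked first, with 3 counts in Sham Veh and 17 in Sham TSA (2.47, 0.68 to 4.88). The lowest included Il1rn, the interleukin-1 receptor antagonist (−0.97, −1.52 to −0.43), Rab6b (−0.61, −0.81 to −0.40), Nrg3 (−1.24) and Apba2 (−1.10), and Mef2c was at −0.68 (−1.36 to −0.01) on 50 and 32 counts. Of the 19 lists 10 stood apart.

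When all 4 libraries entered an additive model, TSA was associated with higher acetylation at 47 promoters and lower acetylation at 2 (edgeR quasi-likelihood test, adjusted p under 0.05). The 47 included Myh6 (log2 fold change 0.63, adjusted p = 1.2e-05), Kcnj3 (0.90, adjusted p = 9.5e-05), Fam174b (0.71), Ces1d (0.80), Actc1 (0.59), Kcnk3 (0.65), Mybpc3 (0.57), Ttn (0.58), Tnnt2 (0.42), Tbx5 (0.55), Cd36 (0.48), Fabp3 (0.42) and Pln (0.47). The 2 lower ones were the basement membrane collagen Col15a1 (−0.47) and Hlx (−0.35). Of the 385 genes in the 19 lists 14 were among the 47, where 0.792 would be expected. Adjusted over the list alone, 14 of 20 adult sarcomere, 8 of 10 cardiomyocyte and 12 of 25 calcium handling promoters were higher with TSA, against 6, 5 and 3 over all genes.

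The surgery effect of the additive fit was past the threshold at 3 promoters higher (Mir101c, Sfi1 and 5730507C01Rik) and 5 lower (Ces1d −0.77, Adh1 −0.74, the lipoprotein lipase gene Lpl −0.38, Slc26a10 −0.40 and 4930449E18Rik −0.41). Scaled counts rose from Sham Veh through Sham TSA and TAC Veh to TAC TSA for Mir101c (582.5, 637, 967 and 1561) and Sfi1 (960, 1024, 1275 and 1679). The share of counts at receptor promoters rose in the same order. For these calls surgery cannot be told apart from a batch, since sham and TAC libraries may not have been made together. Adjusted over the list alone, 7 of 10 cardiomyocyte promoters were lower and 1 higher, against 0 over all genes. This effect averages list medians of −0.60 with vehicle and 0.02 with TSA, so it is not a lowering common to both. DESeq2 called none for either effect, with 47 and 61 promoters at an unadjusted p under 0.05 for surgery and drug, where edgeR had 2128 and 976. The fit assumes that TSA acts alike in sham and TAC hearts, which the ratios of the 47 promoters do not show. Their median was 0.35 in Sham TSA over Sham Veh and 0.78 in TAC TSA over TAC Veh. For 32 of the 47 the difference between these ratios exceeded its counting interval, so their p-values rest on a spread that leaves out their own interaction.

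The interaction, taken as the surgery log2 ratio with TSA minus that with vehicle and given with its counting interval, was 0.88 for Myh6 (0.62 to 1.15), 1.08 for Ces1d (0.59 to 1.58) and 0.87 for Kcnj3 (0.40 to 1.35). It was −0.90 for Postn (−1.42 to −0.39), −1.57 for Thbs4 (−2.29 to −0.85), −1.72 for Serpina3n (−2.25 to −1.19) and −1.32 for C1qb (−1.75 to −0.89). Acta1 (−0.37, −0.89 to 0.15) and Nppb (−0.07, −0.53 to 0.38) had intervals that included 0. By list the median was 0.48 for cardiomyocyte, 0.41 for adult sarcomere and 0.24 for calcium handling genes, −0.26 for matrix, −0.38 for fibroblast and −0.43 for leukocyte genes. With 1 library per group the interaction was not tested.

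Across genes, the ratios of TAC TSA over TAC Veh and of TAC Veh over Sham Veh had a Pearson correlation of −0.25 (Spearman −0.31). The shared TAC Veh library alone gave −0.48 in simulated counts. The covariance was −0.0205 against a simulated −0.0228, a difference of 0.00238. With the TAC Veh reads split at random between the comparisons the correlation was 0.01. With loess scaling the correlation was −0.55 against a simulated −0.48, with a covariance of −0.0352 against −0.0221 simulated. It was −0.16 after the split. At a mean count of at least 30 it was −0.41, and −0.13 after the split. Of the 133 lower in TAC Veh than in Sham Veh, 88 were apart and higher in TAC TSA than in TAC Veh, where 17.3 shared promoters arose in simulated counts and 5.40 with independent lists. Of the 440 higher ones 25 were lower with TSA, against 12.9 simulated and 1.5 with independent lists. The simulated lists held about 99.7 lower and 107 higher promoters for the first overlap, and about 97.2 higher and 113 lower for the second. The simulated overlaps are thus not for lists of the observed sizes. Part of each excess may come from the shared library.

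The surgery ratios with vehicle and with TSA, which share no library, correlated at 0.28 across genes (Spearman 0.19) and at 0.04 with loess scaling. Of the 440 promoters higher with vehicle, 117 were also higher in TAC TSA than in Sham TSA, against 31.7 with independent lists and 1.9 simulated. The simulated lists held about 97.2 and 112 promoters, fewer than the 440 and 1643 observed. With loess scaling 2 were higher in both, so this overlap may follow from the trend with mean count. Lower in both were 12 with loess scaling, against 3.26 with independent lists and 1.7 simulated, and 0 with the main scaling. Also with loess scaling, 13 were higher with vehicle and lower with TSA (2.66 with independent lists, 1.4 simulated), and 3 the other way (2.02 and 1.9). The SD of log2 contrasts over genes was 0.25 for surgery, 0.19 for drug and 0.19 for their interaction, against 0.15 from counting in each. With loess scaling these were 0.18, 0.17 and 0.17. A batch between sham and TAC libraries, if there was one, would enter the surgery contrast and both surgery ratios. The larger spread for surgery and the correlation of 0.28 therefore cannot be assigned to surgery alone.

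The authors also listed regions of the mm9 genome that differ between libraries. In the authors' deposited table for TAC Veh against Sham Veh 1180 regions were higher and 3834 lower, with median widths of 753 and 1014 bp. The authors' deposited table for TAC TSA against Sham TSA held 2349 higher regions (median 519 bp) and 5319 lower ones (1236 bp). For TAC TSA against TAC Veh the authors' deposited table held 2164 higher regions (653 bp) and 3420 lower ones (1058.5 bp). Lower regions thus outnumbered higher ones in each of these comparisons, whereas more promoters were apart and higher than lower with TMM scaling. The top-scoring region lower in TAC Veh in the authors' deposited table lay on chromosome 14 from 55575132 to 55585582, with a score of 599. In the authors' deposited table of regions higher in TAC TSA, the same interval on chromosome 13, from 74665800 to 74668640, ranked second against Sham TSA (score 459) and first against TAC Veh (score 346). The genes at these regions were not assigned, since an annotation of this build was not used here.

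Of the 3834 regions lower in TAC Veh than in Sham Veh, 350 overlapped a region higher in TAC TSA than in TAC Veh, where 8.02 did with random placement, and 5 overlapped a region lower there. Of the 1180 regions higher in TAC Veh, 390 overlapped a region lower in TAC TSA than in TAC Veh, against 3.62 at random. Another 10 (3 on autosomes) overlapped a region higher there, against 1.84 at random. All 390 had identical start and end positions in both lists. The counts of 350 and 390 compare lists that share the TAC Veh library, which favours overlap in opposite directions, and placement at random does not take this into account. Between the surgery comparisons with vehicle and with TSA, which share no library, 242 regions were lower in both (26.3 at random) and 76 higher in both (2.56 at random). On autosomes these were 240 and 32. A further 30 regions were higher with vehicle and lower with TSA (6.22 at random), and 12 lower with vehicle and higher with TSA (7.34 at random). Random placement was uniform along chromosomes and not limited to acetylated regions. An excess over it therefore does not by itself show an effect of surgery common to both comparisons. A batch between sham and TAC libraries could also be shared by both.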

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

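The tests of explanations in this part were chosen after the results were seen, and with 1 library per group none of the differences between groups was tested. Gene lists whose ratios stood apart from count-matched lists on opposite sides in paired comparisons are given as the second difference from matched lists minus the first. For surgery, with TSA minus with vehicle, the value was 0.701 for cardiomyocyte markers (−0.59 with vehicle, 0.12 with TSA), 0.566 for adult sarcomere genes (−0.39 and 0.18) and −0.595 for leukocyte markers (0.28 and −0.31). For the drug, in TAC minus in Sham, it was −0.491 for leukocyte markers (0.24 in Sham, −0.25 in TAC), −0.33 for fibroblast markers (0.11 and −0.22) and 0.165 for endothelial markers (−0.07 and 0.09). No anchor gene had intervals on opposite sides of 0 in either pair.

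Heart muscle promoters were lower in TAC Veh than in Sham Veh and in TAC TSA. A trend with mean count does not account for this, because after loess scaling the cardiomyocyte list still lay −0.584 from its count-matched lists. A batch shared by both sham libraries would by itself lower the list in TAC TSA too, where it lay 0.115 above its matched lists in TAC TSA over Sham TSA (lower bootstrap bound over genes 0.02). A lower share of cardiomyocytes, with the other cells in fixed ratio, would raise markers of the other cell types alike. The endothelial median instead lay −0.423 from the fibroblast median (bootstrap interval over genes −0.62 to −0.22). That speaks only to a fixed ratio. A change in the shares of several cell types at once, or in fibroblasts themselves, stays open. A peculiarity of the 1 TAC Veh library, such as the piece of ventricle taken, cannot be told apart from pressure overload, since there is no second TAC Veh library. An effect of TAC on acetylation that TSA prevents may therefore be stated only as a hypothesis.

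Leukocyte promoters were higher with TSA in Sham and lower with TSA in TAC. A trend with mean count does not account for the second part, as the list lay −0.264 from its matched lists in TAC TSA over TAC Veh after loess scaling (0.25 in Sham TSA over Sham Veh). A different share of leukocytes in the tissue may lie behind both parts. Macrophage and complement promoters outside the list had medians of −0.339 in TAC TSA over TAC Veh and 0.35 in Sham TSA over Sham Veh, but these 26 genes were chosen after their values were seen. A share of cells and acetylation per cell cannot be told apart from these counts.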

How the results depend on the processing

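All alternatives were listed before the data were examined except the restriction to the upper part of mean counts, which was chosen after seeing the data. Counts of promoters apart are given as higher and lower. Silent-promoter scaling moved the median of all genes by −0.24 in TAC Veh over Sham Veh, −0.61 in TAC TSA over Sham TSA and −0.38 in TAC TSA over TAC Veh, and gave 116 and 879, 102 and 12009, and 100 and 3289. It assumes that background reads are equal. The sign of any ratio smaller than these shifts depends on that choice, and the excess turned toward lower in each of these comparisons. Loess scaling, which removes the trend with mean count by construction, gave 199 and 244, 189 and 305, and 301 and 243 in the same order. Total-count scaling gave 31 lower in TAC TSA over Sham TSA and 50 in TAC TSA over TAC Veh. A 2-fold threshold, which counts fewer by construction, gave 189 and 15, 680 and 4, 289 and 2, and 45 and 32 in Sham TSA over Sham Veh. A mean count of at least 30, which removes weak promoters, gave 273 higher in TAC Veh over Sham Veh and 86 higher in Sham TSA over Sham Veh. The upper part of mean counts alone held 6 and 43, 3 and 11, 73 and 13, and 1 and 1. The direction of the excess in TAC Veh over Sham Veh and TAC TSA over Sham TSA thus depended on weak promoters. In TAC TSA over TAC Veh it stayed toward higher in the upper part and with loess scaling, but turned toward lower with silent-promoter scaling.

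The number of lists standing apart changed by over 1.5 times only in TAC TSA over Sham TSA, to 5 with loess scaling. None of the 380 values of single lists under alternatives moved beyond the spread of matched lists, but scalings with 1 factor per library cannot move a difference from matched lists, so only loess scaling and the filter bear on this. For the additive fit DESeq2 gave 0 and 0 for surgery and 0 and 0 for the drug; the cause was not tested. Total-count scaling gave 2 lower for surgery and 75 and 4 for the drug, and a mean count of at least 30 gave 4 lower for the drug. The correlation of surgery ratios was 0.0401 with loess scaling and 0.177 at a mean count of at least 30, and that between the TSA and surgery ratios −0.549 and −0.408. The correlation of drug ratios in Sham and TAC was −0.0017 and became 0.0028 with a prior count of 0.5, both near 0. The upper part of the authors' score, which keeps fewer regions by construction, left 590, 1175 and 1083 higher and 1917, 2662 and 1711 lower regions in the authors' deposited tables for TAC Veh over Sham Veh, TAC TSA over Sham TSA and TAC TSA over TAC Veh.

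Of the other values for single genes and overlaps 624 stayed within their spread, 101 moved and 1, the correlation of drug ratios above, was counted as reversed. Single genes could count as reversed only where apart in the main setting. DESeq2 and total-count scaling shift all genes of a comparison alike and by little, so single-gene values that stayed under them carry little weight. The correlation of TSA and surgery ratios after the split of TAC Veh reads also changed sign. It went from 0.01 to −0.16 with loess scaling and −0.13 at a mean count of at least 30. The TAC TSA library had the lowest depth. In TAC Veh over Sham Veh the 1.5-fold rule found 50% of promoters simulated with a 1.5-fold difference. This share follows from a threshold placed at the simulated difference and is not a measure of depth.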

Other observations

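The gene lists of this paragraph and the tests of explanations below were chosen after the values were seen, while the receptor list and the thinning of counts were fixed beforehand. Promoters of muscle microRNAs and their host transcripts (10 genes) had medians of −0.67 in TAC Veh over Sham Veh, 0.89 in TAC TSA over TAC Veh, −0.02 in TAC TSA over Sham TSA and 0.13 in Sham TSA over Sham Veh. Mhrt, a transcript antisense to Myh6 that shares its locus, was at 1.00 (0.80 to 1.20) in TAC TSA over TAC Veh, and Mir133a-2 at 1.09 (0.68 to 1.52). Macrophage and complement genes (26) had medians of 0.28, −0.34, −0.40 and 0.35 in the same order of comparisons. C1qb and Mpeg1 (−0.68, −1.10 to −0.28) were among those apart and lower in TAC TSA than in TAC Veh. C1qa (−0.50, −0.84 to −0.17) had an interval below 0 without reaching 1.5-fold. Interferon-stimulated genes (27) were at −0.03, −0.19, −0.33 and 0.10. Oasl2 was at −0.54 (−0.77 to −0.32) and Irf9 at −0.44 (−0.64 to −0.24) in TAC TSA over TAC Veh, neither 1.5-fold lower. The 38 Hox genes, developmental regulators, were at 0.07, −0.03, 0.04 and −0.02. Against count-matched lists they were lower in TAC TSA over TAC Veh (difference −0.16, percentile 0.12) and in TAC TSA over Sham TSA (difference −0.12, percentile 1.6).

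Weak promoters were higher in TAC TSA, and a constant number of background reads added at every promoter stays open as an explanation. The best such line (11.9 added reads) missed the observed medians of deciles of mean count by up to 0.0909 on the log2 scale, and the bootstrap interval of this gap (0.08 to 0.12) includes the bound of 0.1 set for it. Lower depth does not account for it, since 1450 promoters were apart and higher in TAC TSA than in Sham TSA after all libraries were thinned to the smallest total, against 124.5 in counts simulated without a difference at that depth. TSA raising acetylation at silent promoters in any heart would also show in Sham TSA over Sham Veh, where receptor promoters had a median of 0.0692 against 0.41 in TAC TSA over TAC Veh. An action of TSA at silent promoters limited to TAC hearts may also remain.

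Regions on chromosome X made up 6.10% and 9.24% of the regions higher in TAC Veh than Sham Veh and in TAC TSA than Sham TSA in the authors' deposited tables. They made up 0.965% and 1.65% of the lower ones in the authors' deposited tables. For TAC TSA against TAC Veh, the authors' deposited tables held 2.77% of higher and 1.87% of lower regions on X. Chromosome Y held 21, 44 and 13 of the higher regions in the authors' deposited tables for TAC Veh against Sham Veh, TAC TSA against Sham TSA and TAC TSA against TAC Veh. It held 0, 1 and 0 of the lower ones in the authors' deposited tables, so the imbalance was not particular to X. The 814 X-linked promoters had medians of 0.03, −0.01 and −0.02 in TAC Veh over Sham Veh, TAC TSA over Sham TSA and TAC TSA over TAC Veh. The 5 Y-linked promoters had medians of −0.16, −0.12 and 0.04 in the same order, so they were not higher in either surgery comparison.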
